A study of Mus musculus with 4 samples.

How the data were processed

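Brains of 6-week-old C57BL/6N mice were compared between 2 genotypes, wild type and homozygous for a CRISPR-Cas9 knock-in point mutation of Wdr4, with 2 libraries each. RNA was extracted with TRIzol and polyadenylated RNA was made into stranded Illumina libraries, per the labels' protocols. The labels do not say whether each library came from 1 animal, so p-values measure the spread between these libraries, which may be partly technical. The genotype and the replicate number of each library were taken from its title, and no column of the table was without a library.

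The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped reads), with 2 decimals, for 18138 rows named by gene symbol. Per the submitters' processing notes, TopHat2, HTSeq and the mm10 build were used. Their versions, the gene annotation, the transcript length behind each FPKM and whether the counting used strand are not given in the sources used here, so overlapping genes and genes with near-identical copies are uncertain. The table had 18136 distinct symbols, of which 17690 matched RefSeq GRCm38.p6, the assembly behind mm10, and 17514 of these were protein coding. Of the rows, 34 carried a symbol made only of digits, and 24 of those were 5-digit numbers of the kind a spreadsheet makes from month-like gene names. Digit-only rows stayed in the tests and were not named. Mitochondrially encoded mRNAs and Xist are not analysed here.

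Depth was estimated from the low FPKM values, because an FPKM times the transcript length is a whole number of reads divided by the depth. Over 502 to 558 genes with 1 annotated transcript (GENCODE vM21, shorter than 2500 bases, FPKM of 0.03 to 0.6), the depth that made most values whole was 19700000 reads in wild type 1, 19700000 in wild type 2, 18200000 in mutant 1 and 18700000 in mutant 2. At these depths 54.9% to 61.2% of the values lay within 0.15 of a whole number, against 30% by chance. The steps were too blurred to recover counts for nearly all genes, so no count test was run. In genes with at least 200 estimated reads, chi-square per degree of freedom was 5.16 between the wild type libraries and 8.48 between the mutant libraries, so replicates differed by more than counting noise and were kept as separate samples.

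The design had been fixed for counts, with a second route for normalized values, before the data were examined. The values were FPKM, so the second route was used throughout. Genes with an FPKM of at least 1 in at least 2 libraries were kept (12811 genes). The values were moved to log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on level), with genotype as the only term and two-sided p-values adjusted by the Benjamini-Hochberg method over all genes tested. The threshold was an adjusted p of 0.05. Fold changes on this scale are mutant minus wild type, and they understate the change of genes with low values. With 2 residual degrees of freedom per gene, the test leans on the spread shared across genes. A single exact permutation test of 2 against 2 libraries cannot go below a two-sided share of 0.333, so none is given for single genes.

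Gene lists for pathways, brain cell types and brain regions were fixed before the data were examined (38 lists). The 35 lists with at least 5 tested members, sex chromosome genes left out, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 35 lists. Camera was repeated with an estimated correlation, and fry was run on the same lists. Named genes were set by a rule fixed at the same time. Wdr4 and Mettl1 are always named. The 12 genes with the largest fold change in each direction are named if they passed the threshold, had groups that did not overlap and had a mean of at least 1 FPKM, leaving out predicted genes without a standard name. Up to 4 members with the smallest p are named for each list past the threshold and for the lists of p53 targets, cell cycle, primary microcephaly, synapse and tRNA, rRNA or cap modification. A gene outside the rule is described as chosen after its values were seen.

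GC content and length of the longest protein-coding transcript per symbol were taken from GENCODE vM21 and were known for 99% of the tested genes and 98.9% of the called ones. A loess trend on GC content and log2 length (span 0.4) was removed from each library as an added alternative. Lists of transcripts restricted to kidney and 6 other organs (liver, striated muscle, exocrine pancreas, testis, lung and intestine), and lists of cerebellar granule and Purkinje cell genes, were written after the gene table was first seen. Fisher's exact test and chi-square tests used scipy 1.17.1 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9. Permutation tests of gene lists drew 100000 resamples.

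The limma step was tested on simulated data for this comparison, with 200 of 12811 genes changed. It called 28% of genes changed by 1.25 fold, 84% of those changed by 1.5 fold and 100% of those changed by 2 or 4 fold, and 7.7% of its calls were unchanged genes. In a simulated list test over the same 12811 genes, a list raised by 0.3 log2 units was called and 0 of 40 random lists were. Genes were simulated as independent, with spread drawn from the fit's own prior, so the 0 of 40 does not cover lists of correlated genes. Estimated correlations in the tested lists reached 0.83, for interferon. Changed genes were drawn only from above a level higher than the filter, so the shares called do not describe genes near the filter. With a simulated GC trend over 12680 genes, 400 unchanged genes were called before the trend was removed and 13 after.

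The alternatives were median-of-ratios and upper quartile scaling of the FPKM, no filter on low values, a pseudocount of 0.1, a robust variance prior, the replicate number as a block, a test against a log2 fold change of 0.5 and leaving out each library in turn. For the lists they also included the estimated correlation, ranks and fry. Removal of the GC and length trend, with and without the block, leaving out chromosomes X and Y, and a mean FPKM of at least 5 were added after seeing the data.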

Results

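Gene expression was measured by sequencing polyadenylated RNA from the brains of 6-week-old mice. The comparison asks which transcripts differ between wild type brains and brains homozygous for a point mutation in Wdr4. Wdr4 is the partner of Mettl1, the enzyme that places N7-methylguanosine on tRNA. Each genotype had 2 libraries, and values are FPKM. The estimated depth was 18200000 to 19700000 reads per library, and 17058 to 17181 genes had an FPKM above 0. Pearson's r of log2(FPKM + 1) over the tested genes, which are not independent replicates, was 0.9966 between the wild type libraries, 0.9957 between the mutant libraries and 0.986 to 0.989 between genotypes.

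No difference in Wdr4 mRNA was detected between the genotypes. Its FPKM was 5.44 and 5.01 in the wild type libraries and 5.46 and 6.18 in the mutant libraries, a log2 fold change of 0.13 ± 0.10 (SE, limma, adjusted p = 0.378). A knock-in of a coding change need not alter the mRNA level, so these values do not check the labels. Wdr4 lies on chromosome 17 (31494322 to 31519985, mm10). Mettl1, on chromosome 10 (127041549 to 127046365), had 9.17 ± 0.18 FPKM in wild type and 9.28 ± 1.57 in mutant libraries (SD, n = 2 each), a log2 fold change of 0.01 ± 0.11 (SE, limma, adjusted p = 0.969). Of 185 tested genes that start within 5 Mb of Wdr4, 40 passed the threshold (21.6%), against 24.5% of all tested genes.

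The libraries also differed between genotypes in sex-linked transcripts and in kidney transcripts. The Y-linked gene Ddx3y had FPKM of 0 and 0.01 in the wild type libraries and 6.6 and 6.07 in the mutant libraries, and Kdm5d had 0 and 0.01 against 1.47 and 1.58. Eif2s3x, an X-linked gene that escapes inactivation, had 45.99 and 47.73 in wild type against 29.75 and 30 in mutant libraries. Other X-linked genes that escape did not all follow: Kdm5c had 9.78 and 9.02 against 7.59 and 8.32, Ddx3x 33.42 and 37.49 against 33.88 and 37.5, and Kdm6a 1.75 and 1.77 against 1.82 and 2.06. Wild type libraries carried almost no Y-linked mRNA and mutant libraries did, so sex coincided with genotype in all 4 libraries and applies to each difference given here. Slc34a1, the phosphate cotransporter of the kidney proximal tubule, had FPKM of 13.06 and 11.87 in the wild type libraries and 0.06 and 0.05 in the mutant libraries. Kap, a kidney androgen-regulated transcript, had 16.2 and 13.01 in wild type and 0.27 in mutant 2, and was listed at 0 in mutant 1.

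Across the transcriptome, many genes differed by small amounts and few by large ones. Of 12811 genes tested, 3141 passed the threshold in limma, 2007 higher and 1134 lower in the mutant libraries. Fold changes of at least 2 in mean FPKM were found for 142 of the higher and 40 of the lower genes, and 1357 higher and 994 lower genes had a log2 fold change smaller than 0.5 in size. The values of the 2 genotypes were fully separated in each of the 3141 called genes and in 64% of all tested genes, where chance gives 33.3%. Higher genes had a lower median GC content (43.9%) than lower genes (54.6%), and all tested genes had 50.6%. Once a trend on GC content and length was removed from each library, limma called 1002 genes higher and 1363 lower. Of these, 890 and 876 had been called in the same direction before, and the share of higher calls went from 63.9% to 42.4%. Scaling alone also reduced the excess of higher calls. Limma called 1750 genes higher and 1325 lower with median-of-ratios scaling, and 1723 and 1451 with upper quartile scaling. The count depended on single libraries, with 995 calls without wild type 1 and 1961 without wild type 2, and 60 genes passed a test against a log2 fold change of 0.5.

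**Figure D1:**
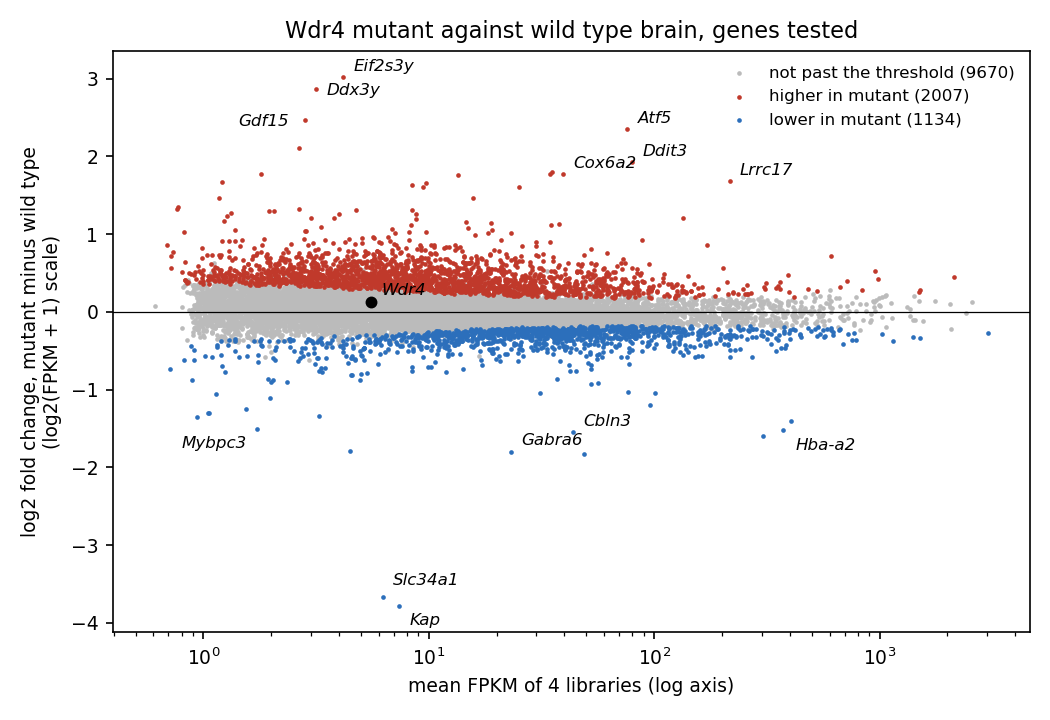
Log2 fold change (mutant minus wild type, on the log2(FPKM + 1) scale) of each of the 12811 tested genes against its mean FPKM over 4 libraries on a log axis. Points are coloured by call, 2007 higher and 1134 lower in mutant; Eif2s3y and Ddx3y are Y-linked, and Wdr4 (black) lies near 0.

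Of the 12 largest increases, 6 were stress response genes. Gdf15, a secreted stress cytokine, had FPKM of 0.165 ± 0.0354 in wild type and 5.48 ± 0.948 in mutant libraries, a log2 fold change of 2.47 ± 0.13 (SE). Atf5, a transcription factor, rose 5.3 fold from 24.2 ± 2.51 to 128 ± 16.9 FPKM, and Ddit3, which encodes the transcription factor CHOP, rose 3.89 fold from 32.8 ± 1.73 to 128 ± 1.12 FPKM (SD, n = 2 each). In mm10, Gdf15 lies on chromosome 8 (70629393 to 70632470), Atf5 on chromosome 7 (44812256 to 44816658) and Ddit3 on chromosome 10 (127290793 to 127296291). Nupr1 rose by 1.79 ± 0.17, Trib3 by 1.77 ± 0.13 and Chac1, an enzyme that degrades glutathione, by 1.77 ± 0.11 on the log2 scale (SE). The others were the Y-linked Eif2s3y (3.02 ± 0.12) and Ddx3y (2.87 ± 0.11), Cox6a2, a striated muscle subunit of cytochrome c oxidase (1.77 ± 0.09), Cyb5r1 (1.77 ± 0.08), Lrrc17 (1.69 ± 0.30) and Cst7 (1.67 ± 0.14). All had a limma adjusted p of at most 0.00362, the value of Lrrc17, whose FPKM was 106 ± 58 in wild type and 326 ± 95.4 in mutant libraries; without wild type 2 its log2 fold change was 1.11. With a robust variance prior, Lrrc17 (adjusted p = 0.221) and Nupr1 (adjusted p = 0.0613) no longer passed in limma. The size of changes from low values depends on the pseudocount; at 0.1 in place of 1 the log2 fold change was 4.39 for Gdf15, 3.24 for Trib3, 4.11 for Cst7, 5.27 for Eif2s3y and 5.94 for Ddx3y.

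Of the 12 largest decreases, 10 were kidney, blood or cerebellar transcripts. Kap (log2 fold change -3.78 ± 0.14, SE) and Slc34a1 (-3.67 ± 0.11) led, and Klk1, a kallikrein abundant in kidney, fell by 1.31 ± 0.22. The red cell lineage gave 5 genes, the haemoglobin genes Hbb-bt (-1.83 ± 0.25), Hba-a1 (-1.60 ± 0.28), Hba-a2 (-1.51 ± 0.14) and Hbb-bs (-1.41 ± 0.15), and Alas2, the erythroid enzyme of haem synthesis (-1.34 ± 0.13). The haemoglobin copies share reads, so the split between them is uncertain, and without mutant 1 the log2 fold change of Hba-a1 was -0.975. Gabra6, a GABA receptor subunit of cerebellar granule cells, fell from 36.5 ± 2.09 to 9.81 ± 1.08 FPKM, and Cbln3, a secreted granule cell protein, from 65.5 ± 2.27 to 21.8 ± 0.431 (SD, n = 2 each). Gabra6 lies on chromosome 11 (42306437 to 42321072), Cbln3 on chromosome 14 (55878920 to 55884256), Slc34a1 on chromosome 13 (55399622 to 55414695) and Kap on chromosome 6 (133849855 to 133853667). Crtam, a surface protein of activated lymphocytes, fell by 1.79 ± 0.14 and Mybpc3, cardiac myosin-binding protein C, by 1.51 ± 0.12 on the log2 scale (SE). With a pseudocount of 0.1 the log2 fold change was -6.25 for Kap, -6.34 for Slc34a1, -2.93 for Klk1 and -2.59 for Mybpc3. The highest limma adjusted p among these 12 genes was 0.00383, for Hba-a1.

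Of the 35 gene lists tested with camera, 12 passed the threshold, 7 higher and 5 lower in the mutant libraries. At an estimated inter-gene correlation none of the 12 kept its call, and those p-values stand beside each list. With an estimated correlation, camera takes its degrees of freedom from the residual ones, here 2. With a preset correlation it takes them from the number of genes. At 2 degrees of freedom the test has little power, so a lost call says little about a list. The size of the correlation does not account for the losses in all lists. The endothelial estimate was 0.011, near the preset of 0.01, yet its camera adjusted p went from 0.0122 to 0.527. For gliosis the estimate was -0.049 and the camera adjusted p went from 9.94e-08 to 0.391. Other estimates were larger, such as 0.83 for interferon. Fry, which tests whether a list moves on balance in one direction, called 3 lists, the integrated stress response (adjusted p = 0.0156), cerebellum (adjusted p = 0.0361) and gliosis (adjusted p = 0.015).

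Targets of the integrated stress response, driven by the transcription factors ATF4 and CHOP, rose together. Of 34 tested members 28 rose, 1 fell and 5 did not pass, with the same 28 and 1 when adjusted over the list alone, and the median log2 fold change was 0.81 (camera adjusted p = 4.45e-18; adjusted p = 0.391 with an estimated correlation). Besides Ddit3, Atf5 and Gdf15, the members with the smallest p included Eif4ebp1, a repressor of cap-dependent translation, which rose 3.54 fold from 4.14 ± 0.219 to 14.7 ± 1.42 FPKM (SD, n = 2 each). The member that fell was Ddit4 (-0.30 ± 0.09, SE, limma adjusted p = 0.0287), named after its value was seen. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, also rose, with 12 of 20 members higher and 0 lower, or 14 higher and 1 lower when adjusted over the list alone (median 0.31, camera adjusted p = 0.000125; adjusted p = 0.527 with an estimated correlation). Cars rose by 1.15 ± 0.07, Aars by 0.68 ± 0.07, Mars by 0.68 ± 0.07 and Yars by 0.61 ± 0.06 on the log2 scale (SE).

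**Figure D2:**
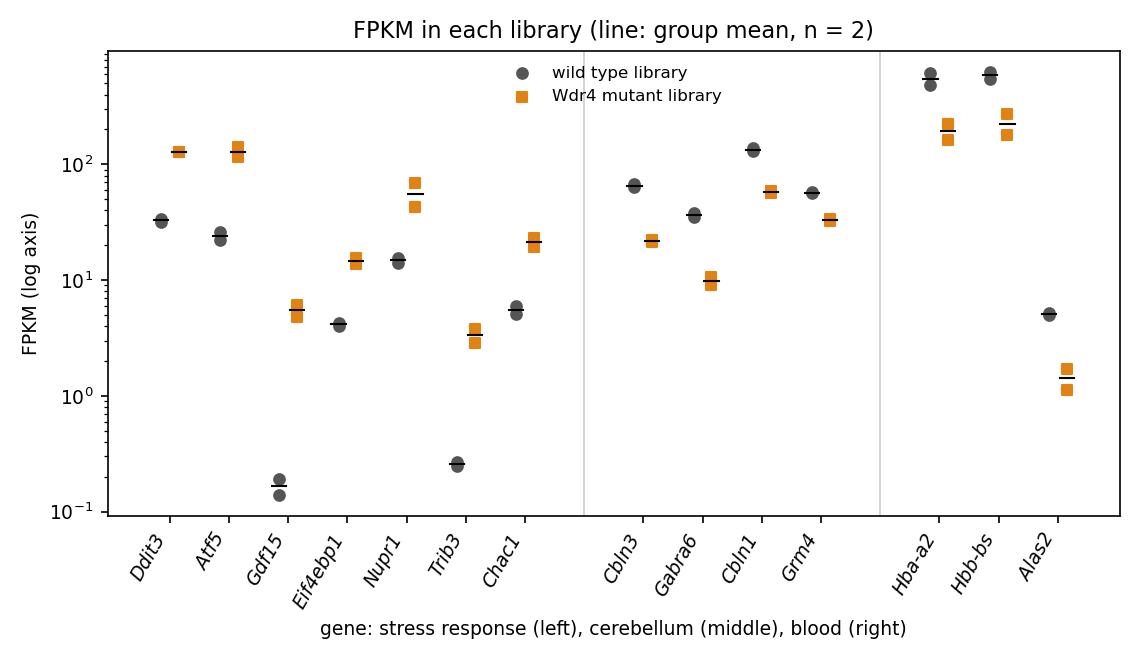
FPKM on a log axis of named genes in each wild type library (circles) and Wdr4 mutant library (squares), with short lines at the group means of 2 libraries. The stress response genes at the left lie higher in both mutant libraries, such as Ddit3 at 126.68 and 128.27, and the cerebellum and blood genes lie lower.

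Transcripts of reactive glia and inflammation were higher in the mutant libraries. In that list 12 of 15 members rose and 0 fell, or 13 when adjusted over the list alone, with a median of 0.73 (camera adjusted p = 9.94e-08; adjusted p = 0.391 with an estimated correlation). Serpina3n rose 1.71 fold from 16.3 ± 0.156 to 27.9 ± 0.997 FPKM, the chemokine gene Cxcl10 rose from 0.375 ± 0.0636 to 2.1 ± 0.0707 FPKM and Lcn2 from 0.36 ± 0.0849 to 2.19 ± 0.325 FPKM (SD, n = 2 each). Cst7, a protease inhibitor of activated microglia, is also in this list. Of 11 interferon-induced genes 7 rose and 0 fell, also when adjusted over the list alone (median 0.46, camera adjusted p = 0.00225; adjusted p = 0.891 with an estimated correlation). Bst2 rose by 1.20 ± 0.11, Isg15 by 0.80 ± 0.12, Ifit3 by 0.71 ± 0.14 and Lgals3bp by 0.34 ± 0.08 on the log2 scale (SE). The interferon list missed the threshold without mutant 2 (adjusted p = 0.0509), and the limma call of Lgals3bp was lost without wild type 1, wild type 2 or mutant 2.

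Microglial and endothelial markers also differed in the same libraries. Of 18 microglial genes 7 rose and 1 fell, or 9 and 1 when adjusted over the list alone (median 0.28, camera adjusted p = 0.038; adjusted p = 0.971 with an estimated correlation). Cd68 rose by 0.42 ± 0.08, C1qb by 0.42 ± 0.08 and Trem2 by 0.40 ± 0.08 on the log2 scale (SE), while the homeostatic marker Tmem119, named after its value was seen, fell by 0.46 ± 0.11. Without mutant 1 the microglial list had a camera adjusted p of 0.352 and without wild type 2 one of 0.0838, and the limma call of Trem2 was lost without wild type 1 (adjusted p = 0.0826) and without mutant 1 (adjusted p = 0.0517). Of 17 endothelial genes 8 rose and 0 fell, also when adjusted over the list alone (median 0.34, camera adjusted p = 0.0122; adjusted p = 0.527 with an estimated correlation). The endothelial median was 0.18 after GC correction (adjusted p = 0.00308), and at a mean FPKM of at least 5, with 6 members tested, the list lost its call (adjusted p = 0.183). The tight junction gene Cldn5 rose 2.13 fold from 11.7 ± 1.82 to 24.8 ± 5.63 FPKM (SD, n = 2 each), and Slco1a4 (0.65 ± 0.11), Esam (0.57 ± 0.12) and Slc2a1, the glucose transporter of the blood-brain barrier (0.39 ± 0.07), also rose on the log2 scale (SE); after GC correction Slco1a4 rose by 0.37.

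Cerebellar transcripts were lower in the mutant libraries. Of 19 tested genes of granule and Purkinje cells 14 fell and 0 rose, or 15 fell when adjusted over the list alone, with a median of -0.50 (camera adjusted p = 3.96e-12; adjusted p = 0.391 with an estimated correlation). Besides Gabra6 and Cbln3, the synapse organizer Cbln1 fell 2.31 fold from 134 ± 6.17 to 57.7 ± 1.42 FPKM and the glutamate receptor Grm4 from 56.8 ± 0.948 to 33 ± 0.983 FPKM (SD, n = 2 each). Genes of striatal medium spiny neurons went both ways, with 6 of 17 lower and 1 higher, the same when adjusted over the list alone (median -0.06, camera adjusted p = 0.038; adjusted p = 0.891 with an estimated correlation). Adora2a fell by 0.42 ± 0.08 and Gng7 by 0.31 ± 0.07, whereas the dopamine receptor gene Drd1 rose by 0.38 ± 0.09 on the log2 scale (SE). The striatal list lost its call without wild type 2 (adjusted p = 0.0643), without mutant 2 (adjusted p = 0.241), on ranks (adjusted p = 0.0852), at a mean FPKM of at least 5 (adjusted p = 0.0706) and after GC correction (adjusted p = 0.155, median -0.10). Adora2a, Gng7 and Drd1 lost their limma calls without wild type 1, and Drd1 also without mutant 1 and after GC correction.

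Blood transcripts, cholesterol synthesis genes and heat shock genes made up the other lower lists. Of 6 blood genes 5 fell and 0 rose, also when adjusted over the list alone (median -1.46, camera adjusted p = 5.28e-06; adjusted p = 0.527 with an estimated correlation), with Hba-a2 at 551 ± 92.6 FPKM in wild type and 194 ± 43.9 in mutant libraries (SD, n = 2 each). The 4 haemoglobin genes lost their limma calls with a robust variance prior, at adjusted p-values from 0.0522 for Hba-a2 to 0.224 for Hba-a1. Of 21 genes of cholesterol synthesis and uptake 14 fell and 0 rose, or 16 fell when adjusted over the list alone (median -0.34, camera adjusted p = 6.78e-09; adjusted p = 0.527 with an estimated correlation). Stard4, a sterol carrier, fell by 0.72 ± 0.10, Nsdhl by 0.54 ± 0.09, Fdps by 0.41 ± 0.06 and Srebf2, the transcription factor of the pathway, by 0.38 ± 0.07 on the log2 scale (SE). Of 16 heat shock genes 5 fell and 0 rose, and the 2 mitochondrial ones (Hspd1 and Hspe1) did not pass over all genes. Adjusted over the list alone, 5 fell and 2 rose, Hspd1 among them. The list had a median of -0.10 (camera adjusted p = 0.038, and 0.891 with an estimated correlation). Hspa1b fell by 0.86 ± 0.16, Hsph1 by 0.38 ± 0.06, Fkbp4 by 0.28 ± 0.06 and Hsp90ab1 by 0.25 ± 0.06 (SE); Hspa1b shares sequence with Hspa1a and is uncertain. The heat shock list lost its call without wild type 2 (adjusted p = 0.154) or mutant 1 (adjusted p = 0.0775) and at a mean FPKM of at least 5 (adjusted p = 0.233). Its median was -0.18 after GC correction. Fkbp4 and Hsp90ab1 lost their limma calls without either wild type library.

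Of 16 circadian clock genes 4 rose and 0 fell, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.038; adjusted p = 0.891 with an estimated correlation). Clock rose by 0.61 ± 0.10, Nr1d2 by 0.52 ± 0.09, Ciart by 0.42 ± 0.08 and Cry1 by 0.28 ± 0.08 on the log2 scale (SE). The clock list lost its call without wild type 1 (adjusted p = 0.0847) or mutant 2 (adjusted p = 0.191) and at a mean FPKM of at least 5 (adjusted p = 0.054). Cry1 lost its limma call whichever library was left out, and Clock lost its call after GC correction (log2 fold change 0.19, adjusted p = 0.138), where Nr1d2 rose by 0.255 (adjusted p = 0.0393).

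**Figure D3:**
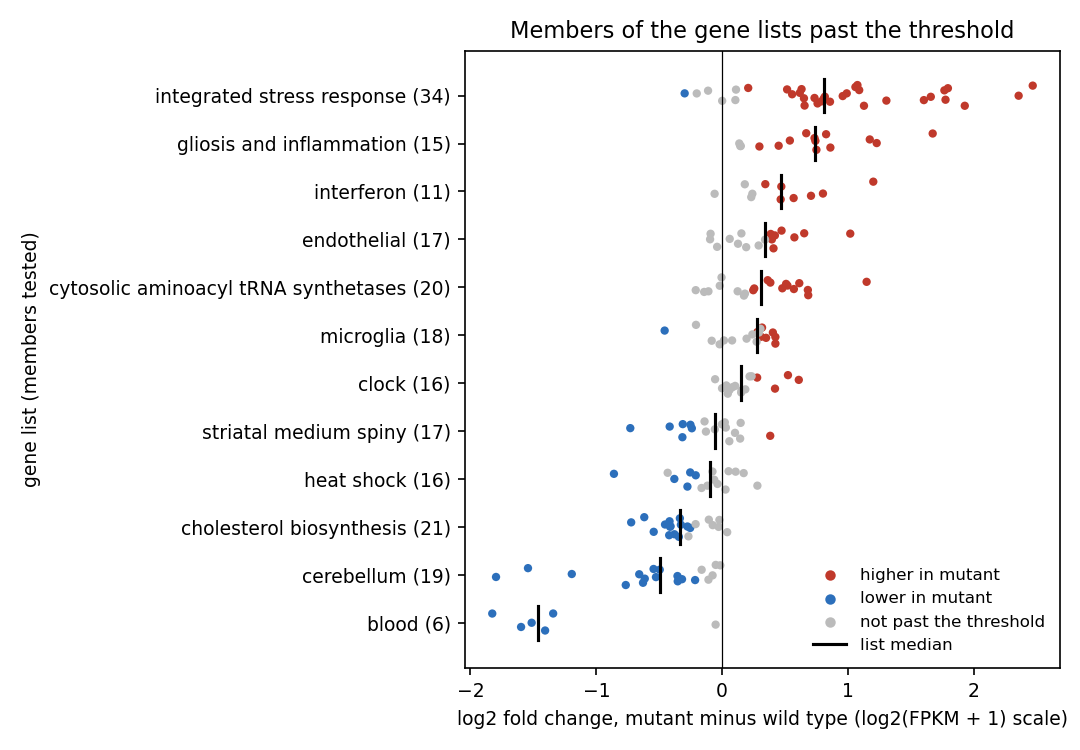
Log2 fold change (mutant minus wild type, on the log2(FPKM + 1) scale) of the tested members of the 12 gene lists past the camera threshold, with 1 point per gene coloured by its limma call and a black bar at each list's median. The medians run from -1.46 for blood to 0.81 for the integrated stress response; points are spread vertically only for display.

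Single members changed in several lists that did not pass as a whole. Among 21 p53 targets 7 rose and 1 fell, or 7 and 2 when adjusted over the list alone (median 0.08, camera adjusted p = 0.17, and adjusted p = 0.0355 without a filter on low values). The cell cycle inhibitor gene Cdkn1a rose 2.23 fold from 21.6 ± 0.622 to 48.2 ± 0.17 FPKM, Bbc3, which encodes the apoptosis protein PUMA, rose 2.4 fold from 4.92 ± 1.04 to 11.8 ± 0.354 FPKM (SD, n = 2 each), Ccng1 rose by 0.50 ± 0.07 and Ddit4l fell by 0.81 ± 0.10 on the log2 scale (SE). Among 40 synaptic genes 10 rose and 5 fell, or 11 and 7 when adjusted over the list alone, and the list's median was -0.01, its mean 0.06 and its camera direction down (adjusted p = 0.835). Gabrb2 (0.73 ± 0.08), Gria3 (0.67 ± 0.09) and Gria2 (0.58 ± 0.07) rose and Syn2 (-0.50 ± 0.06) fell on the log2 scale (SE). After GC correction 5 synaptic genes rose and 12 fell (median -0.09, camera adjusted p = 0.05, not past the threshold). The corrected changes were 0.04 for Gria2 (adjusted p = 0.753), 0.43 for Gria3 and 0.24 for Ccng1.

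Among 15 cell cycle genes 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.976). Mcm7 rose by 0.39 ± 0.10, and log2 fold changes were -0.33 ± 0.11 for Mcm5, 0.32 ± 0.12 for Tpx2 and 0.14 ± 0.06 for Pcna (SE), which did not pass. Mcm5 passed, lower, with median-of-ratios (adjusted p = 0.0384) and upper quartile scaling (adjusted p = 0.0322), a robust prior (adjusted p = 0.0447) and the replicate block (adjusted p = 0.0479). Tpx2 passed without a filter on low values (adjusted p = 0.0493). Of 15 genes of primary microcephaly 2 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.404), among them Cit by 0.28 ± 0.08; Ncapd2 (-0.22 ± 0.10) and Phc1 (0.17 ± 0.09) did not pass. Of 21 genes of tRNA, rRNA and mRNA cap modification 2 rose, Alkbh8 (0.44 ± 0.12) and Pus3 (0.36 ± 0.11), and 0 did when adjusted over the list alone (camera adjusted p = 0.835); Pus7 (0.27 ± 0.10) and Trmt112 (0.16 ± 0.06) did not pass. After GC correction Alkbh8 (log2 fold change 0.03, adjusted p = 0.855) and Pus3 (0.20, adjusted p = 0.229) were not called in limma. Calls of Cit, Mcm7 and Alkbh8 were each lost when some single library was left out, and that of Pus3 whichever library was left out. Pus3 also missed the limma threshold with median-of-ratios (adjusted p = 0.0534) and upper quartile scaling (adjusted p = 0.054). Without a filter on low values, limma did not call Cit (adjusted p = 0.0545), Alkbh8 (adjusted p = 0.0624) or Pus3 (adjusted p = 0.101).

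Other cell type and region markers did not pass as lists in the main analysis. Camera adjusted p-values were 0.353 for astrocytes, 0.363 for mural and leptomeningeal cells, 0.404 for myelin, 0.517 for ependymal cells, 0.559 for the olfactory bulb, 0.829 for neural progenitors, 0.995 for the choroid plexus and 0.976 for glutamatergic neurons, GABAergic interneurons, monoaminergic and cholinergic neurons, hypothalamus, thalamus and oligodendrocyte precursors. Of the remaining lists, immediate early genes had an adjusted p of 0.132 (median 0.23), glucocorticoid-responsive genes 0.404, nuclear genes of oxidative phosphorylation 0.404, the unfolded protein response 0.559 and ribosomal proteins 0.835. The immediate early list passed, higher, after GC correction (adjusted p = 0.00309, median 0.26) and without wild type 2 (adjusted p = 2.49e-07). Without mutant 1 the mural and leptomeningeal list passed, higher (adjusted p = 0.000254), as it did with all libraries under GC correction and the replicate block (adjusted p = 0.0353). Also without mutant 1, the myelin (adjusted p = 0.0333), oxidative phosphorylation (adjusted p = 0.000547) and ribosomal protein lists (adjusted p = 0.000601) passed, lower. The ribosomal protein list passed, higher, without mutant 2 (adjusted p = 0.00476). The pituitary list had 1 tested member, which did not pass, and the 4 tested sex chromosome genes were all higher in the mutant libraries. In 9 lists the median or mean had another sign than the camera test, and 0 of these 9 lists passed the threshold.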

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

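GC and length correction, leaving out chromosomes X and Y, and a mean FPKM of at least 5 were chosen after seeing the data. DESeq2, voom and edgeR with other factors need counts and were not run on FPKM, and library size scaling and the stricter filter equal the analysis as reported. The 3141 genes past the threshold went to between 995 (without wild type 1) and 2143 (without mutant 1) when 1 library was left out, the 2007 higher genes to between 725 and 1435 and the 1134 lower genes to between 270 and 850, with the lone library assumed to vary like the other group. The drop comes with fewer samples. Against a log2 fold change of 0.5, a stricter hypothesis, 60 genes passed (43 higher, 17 lower). After GC and length correction 1002 genes were higher, and 1063 with the replicate number as a block as well. The 12 lists past the threshold became 0 with an estimated correlation, 3 by fry and 7 at a mean FPKM of at least 5 (31 lists tested). With an estimated correlation, lists whose estimate was near or below the preset also lost their calls, such as endothelial (0.011) and gliosis (-0.049). That form of the test rests on the 2 residual degrees of freedom and has little power here. The loss therefore does not show that correlation between genes accounts for the list results. The causes of the other drops were not tested. Wdr4 kept its direction and did not pass in any alternative (log2 fold change 0.05 to 0.21). Same-numbered libraries had a correlation of deviations of -0.007, so no shared shift was seen across all genes. A shared effect on a part of the genes is not excluded, and the labels do not say what the number stands for. The replicate block gave 3560 calls, 3137 of them among the 3141, and 12 lists. Mettl1, not past the threshold, changed sign with median-of-ratios scaling (-0.02), upper quartile scaling (-0.031) and when libraries were left out (-0.15 to 0.16), as did, at adjusted p-values far from the threshold, the cell cycle list (0.926 to 0.976 with libraries left out), the tRNA, rRNA and cap modification list (0.617 to 0.994 with libraries left out, 0.903 at a mean FPKM of at least 5) and the synapse list by fry (0.294). Of 83 other genes in the table of named genes, of which the text names most, 79 kept call and direction with each scaling, 83 with a pseudocount of 0.1 (12 of them with a log2 fold change over 1.5 times as large, among them Cxcl10 at 2.22, Lcn2 at 2.32 and Hspa1b at -1.32), 77 without a filter, 76 with a robust prior, 82 with the block, 78 after GC correction and 37 against a log2 fold change of 0.5; with 1 library left out, 66 to 72 of the 75 to 79 still tested did. These 83 genes leave out only Wdr4 and include Mettl1. Scaling moved the median log2 fold change of all genes from 0.03 to 0.00 or -0.01. At these depths genes near 1 FPKM rest on few reads, and the smallest of the simulated changes were mostly missed.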

Other observations

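Members of glial lists that did not pass as a whole moved in opposite directions; these genes were named after their values were seen. Among astrocyte genes Gfap, the intermediate filament of reactive astrocytes, rose 2.33 fold from 80.5 ± 1.15 to 187 ± 3.53 FPKM (SD, n = 2 each) and the water channel gene Aqp4 rose from 21.9 ± 2.1 to 34.6 ± 4.26 FPKM, while 2 of the 16 tested genes fell. Among 20 myelin genes 4 rose and 6 fell, and without mutant 1 that list passed, lower (camera adjusted p = 0.0333). Outside the lists, the class II antigen presentation gene H2-Aa rose from 1.92 ± 0.0707 to 6.1 ± 1.7 FPKM (SD, n = 2 each), Lyz2, a lysozyme of myeloid cells, rose 2.97 fold and the kinesin gene Kif5b rose 3.25 fold.

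The tests of kidney RNA, of cerebellum dissected, of sex and of the separate kept shares of higher and lower calls were chosen only after the results were seen. Of 40 kidney-restricted genes in the table, 28 had both wild type values above both mutant values (70%, where shuffled labels give 16.7%). Among genes restricted to other organs 10 of 64 did (15.6%, Fisher's exact test, two-sided p = 2.62e-08). RNA from kidney in the wild type libraries is therefore a candidate source. The genes share the same 4 libraries and are not independent replicates, so the p-value does not measure spread between animals. The kidney list was written after the gene table was seen and holds Kap, Slc34a1 and Klk1, which were already among the largest decreases. The most abundant were Kap (16.2 and 13.01 FPKM) and Slc34a1 (13.06 and 11.87), and 6 of the 40 genes had a mutant mean of at least 0.25 FPKM (a cutoff set after the values were seen), so the mutant libraries hold them too; 1, Napsa, is also in the lung list. By organ the counts were 8 of 20 for striated muscle, 1 of 18 for liver and 0 of 8 for exocrine pancreas. They were 1 of 7 for testis, 1 of 4 for lung and 0 of 8 for intestine. Striated muscle stood at 40%, with 0 genes the other way, and was not tested separately. Of all tested genes, 64% had separated groups in either direction, where chance gives 33.3%, though many of the kidney genes lie below the filter. A share above 16.7% alone thus does not mark RNA from an organ. Whether both libraries hold the same kidney RNA mixture cannot be told from these values. Over 10 kidney genes with at least 20 estimated reads, the split between wild type 1 and 2 differed 5 fold between the highest and lowest gene. The splits differed beyond counting error (chi-square test, p = 3.64e-05, chi-square per degree of freedom 4.02). Ordinary genes also exceeded counting error between these libraries (5.16), but they had at least 200 estimated reads. Chi-square at equal relative spread grows with read number, so 4.02 and 5.16 cannot be compared. How kidney RNA would reach the libraries, before or after dissection, stays open.

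Granule cell transcripts fell more than Purkinje cell transcripts. A smaller cerebellum in the mutant brains as dissected would lower both, but 12 of 13 granule genes fell with a median log2 fold change of -0.63, against 3 of 12 Purkinje genes with a median of -0.12, a difference of 0.51 (permutation test over genes, two-sided p = 0.00131), although the Purkinje gene Ppp1r17 fell by 0.50 (0.60 with a GC and length trend removed), close to the granule median, and Pcp2, a Purkinje gene with little expression elsewhere, by 0.32. Several Purkinje genes, Calb1 and Itpr1 among them, are also expressed in other brain regions, which could hide a part of a loss. Most of the granule genes come from the cerebellum list that had already passed. Genes are not independent replicates, so the permutation tests measure spread among the chosen genes and not between animals. With a GC and length trend removed the granule median was -0.69 and 11 granule genes passed, which argues against that trend, while the Purkinje median was -0.20 and 6 of 12 Purkinje genes were lower, so more of them fell but the difference of medians was still 0.49 (permutation p = 0.0005). An effect of the mutation on granule cells, or of sex, stays open as a hypothesis, as does a smaller loss of cerebellum beside it.

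The number of calls may owe a part to a GC trend between libraries, since the log2 fold change fell with GC content (Spearman's rho = -0.44 across genes, which are not independent replicates), and so did the difference between the 2 wild type libraries (rho = -0.31), while that between the 2 mutant libraries hardly changed with it (rho = 0.08), so a trend occurs within the wild type pair. With the trend removed 2365 genes passed, but only 1766 of them were among the 3108 earlier calls that could be compared and kept their direction; these argue against the trend as the source of all calls. Of the lower calls 78% were kept (876 of 1123) and of the higher calls 44.8% (890 of 1985), so for the higher calls the trend stays open as a source. The integrated stress response was little affected, with a median of 0.78 after the correction against 0.81 before and 27 of its 29 calls kept. Sex cannot be told apart from genotype because it coincides with genotype in all 4 libraries, and 2986 genes passed with chromosomes X and Y left out.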
